A study of Mus musculus with 4 samples.

How the data were processed

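Single-cell RNA sequencing was done, per the labels, on retinas of 3-month-old C57BL/6 mice in which a Brn3b (Pou4f2) reporter marks cells with GFP. Dissociated cells were sorted for GFP, and libraries were made with the 10x Chromium 3′ V2 kit and sequenced on an Illumina instrument, per the labels' protocols. The labels name 4 retinas in 1 group. The processing notes in the labels name Cell Ranger, with no version, Seurat 2.2 and the genome build mm10. The tool that made the table, its settings and the way barcodes were called as cells are not given in the sources used here. The deposited values are counts: whole numbers of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. The second deposited table gives a gene symbol for each Ensembl identifier. All barcodes carry the same suffix, and no name ties a barcode to a retina. The matrix was therefore treated as 1 pooled sample without replicates, and no test, standard error or p-value is given. A planned test on counts summed per retina was left out for the same reason.

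The following choices were made before the data were examined: the cell filter, the clustering settings, the gene lists, the thinning rule, the contrasts, the rule for naming genes and the alternatives, except those said below to be later. Barcodes were kept with 500 or more genes and under 10% of UMIs from mitochondrial genes. This removed 538 of 3237 barcodes, 536 of them at or over the mitochondrial maximum. Scrublet, as run in scanpy 1.11.5, called 63 of the 2699 remaining barcodes doublets (2.33%), and 2636 cells were kept. Counts were scaled to 10000 per cell and log-transformed. Genes seen in fewer than 3 cells were left out of the clustering, and so were all 336 genes of the lists, so that no listed gene defined a cluster. Leiden clustering at resolution 1.0 used 2000 variable genes, 30 principal components and 15 neighbours, with seed 0. RGC-like (retinal ganglion cell-like) cells were clustered again with the same settings. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, python-igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

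Clusters were named from marker lists of 14 cell classes: RGC, rod, cone, bipolar, amacrine, horizontal, Müller glia, astrocyte, oligodendrocyte, microglia or macrophage, endothelial cell, pericyte, retinal pigment epithelium and erythrocyte. RGC-like clusters were named from lists of 7 types: ipRGC (intrinsically photosensitive, the melanopsin cells), F-RGC, alpha RGC, ooDSGC (ON-OFF direction-selective), Tbr1/J-RGC, T5/W3-RGC and N-RGC. A name needed 3 or more markers of its list at 2-fold or more, with 5 CPM (UMIs of a gene scaled to an equal total) added to both sides. It also needed no other list to hold more of the cluster's 10 leading genes. Class folds were taken against the lower quartile (percentile 25) of clusters, and type folds against all other clusters together. These naming thresholds were set after the data were seen. The reference was first the median cluster and was changed because a stricter cell filter leaves so many RGC-like clusters that the median is itself RGC-like. Under that filter 595 cells were RGC-like by the median and 754 by the lower quartile, and under the filter used the number was 959 by both. All names are given as "-like", since they rest on markers alone.

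To hold depth equal, each cell was thinned without replacement to 12000 UMIs, the lower quartile of UMIs per RGC-like cell (12162.5) rounded down to a step of 500. This kept 730 RGC-like cells and left out 229. The share of cells with a UMI is given beside that in horizontal-like cells at the same depth, and in all other named classes at 3000 UMIs, a depth every barcode reached. Shares carry exact Clopper-Pearson intervals, CPM values exact Poisson intervals and ratios exact conditional intervals, all at 95% and all for counting error only. Where 1 class had 0 UMIs, a ratio was taken against a floor of 3 counts over the class and is given as a bound, and a share of 0 is given with the limit of 3 counts of the total, in place of the limits of the exact intervals.

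For each of Pou4f1, Eomes, Foxp2 and Cartpt, RGC-like cells with a UMI in the thinned cell were set against those without. Full counts were summed over each class, with the splitting gene left out, and scaled to CPM. The rule for naming genes took the 12 highest and 12 lowest ratios among genes with 100 or more UMIs over both classes, mitochondrial and ribosomal protein genes aside. It also took members of the functional and type lists with a ratio of 1.5 or more either way and 100 or more UMIs. Across the RGC-like clusters of 20 or more cells, it took list members with 100 or more UMIs whose highest cluster was 4-fold or more above the mean of the others, at most 5 per list. Pou4f1, Pou4f2 and Pou4f3 were always named. Which list members in the contrasts are printed with values, and which leading genes stand beside a cluster, was chosen after values were seen, while the counts given cover all members. The 10 functional lists hold transcription factors, voltage-gated channels, neuropeptides and secreted factors, transmitter receptors, calcium-binding proteins, axon cytoskeleton genes, adhesion and guidance genes, injury and regeneration genes, immediate-early and stress genes, and mitochondrially encoded genes. A list's median ratio was placed among those of 10000 random lists whose members were drawn from the 100 genes nearest in total UMIs. This percentile is a description, not a test. Positions are from GENCODE M21 (GRCm38, the assembly of mm10), in which all 374 named or listed genes were found by identifier.

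The contrast step was tested on simulated cells with the real depths and 200 changed genes per contrast, 50 at each fold. The 24 genes named at both ends were changed genes in each of the 4 simulated contrasts. Between 92% and 100% of the intervals at each fold held the true fold. Each simulated cell was drawn from a pooled RGC-like profile, with the splitting gene high in the detected class and absent from the other. The simulation held no cell types and no genes resting on a single cell, and it hardly allowed misplaced cells. It therefore checks the calculation and does not show how well the intervals cover the real cells. Clustering and naming were tested on 800 cells simulated from 4 class profiles, and 100% received their true name. The alternatives were no cell filter, a stricter filter (1000 genes and 5% mitochondrial), doublets kept, resolutions 0.5 and 2.0, listed genes kept in the clustering, 6000 UMIs or no thinning, scaling by the median of ratios, no low-count filter, and classes by 2 or more UMIs. Cartpt classes by 10 or more UMIs, the rod-gene-led cluster nearest to RGC counted as RGC-like, class names by the median cluster, and the mitochondrial and gene parts of the stricter filter each alone were added after the data were seen. The deposited barcode list was not used, as it repeats the header of the matrix. Results of several genes that met the rule, and a test that rests on such a gene, are not reported here.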

Results

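Gene expression was measured in single cells sorted for GFP from the retinas of adult mice carrying a reporter for Brn3b, the protein encoded by Pou4f2. The 4 retinas form 1 group, and the pooled matrix held 3237 barcodes without replicates. It contained 31361961 unique molecular identifiers (UMIs), between 3198 and 53709 per barcode with a median of 7674, and a median of 2946 detected genes. Intervals in the text are 95% intervals and cover counting error only. The series concerns the diversity of retinal ganglion cell (RGC) types, and the comparisons below describe the cells in the sort, the 3 POU4F genes, the RGC-like clusters and 4 divisions of the RGC-like cells by 1 gene each.

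RGC-like cells were the most numerous class in the sort, but they made up 36.4% of the 2636 cells kept (959 cells, interval 34.5% to 38.3%). Horizontal-like cells, named from Lhx1, Onecut1, Calb1 and Sept4, followed with 21.3% (561 cells, 19.7% to 22.9%). Bipolar-like cells (Trpm1, Pcp2, Grm6 and others) made up 14.5% and Müller glia-like cells (Rlbp1, Slc1a3 and others) 9.03%. These shares depend on the mitochondrial filter: under a maximum of 5% in place of 10%, with nothing else changed, RGC-like cells were 65.4% and horizontal-like cells 3.90%. The order also depends on the filter, as bipolar-like cells (668) outnumbered horizontal-like cells (618) without it. The median mitochondrial share was 3.92% in RGC-like and 6.92% in horizontal-like cells.

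The smaller classes were microglia or macrophage-like cells (6.15%), amacrine-like cells (4.97%), cone-like cells (3.72%), rod-like cells (1.63%) and endothelial-like cells (0.455%). The larger amacrine-like cluster, of 91 cells, was led by Vip and also by Ttr and Rgr, which are on the pigment epithelium list. Ttr and Rgr rested on few cells, as they were found in 2.29% and 0.763% of the 131 amacrine-like cells. A further 50 cells (1.90%) in 2 clusters stayed without a name: 34 paired RGC markers with rod genes and 16 paired horizontal cell markers with rod genes. No cluster met the rule for astrocytes, oligodendrocytes, pericytes, pigment epithelium or erythrocytes. Depth differed between the classes, with a median of 15365 UMIs per RGC-like cell, 10987 per horizontal-like cell and 4307 per bipolar-like cell.

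**Figure D1:**
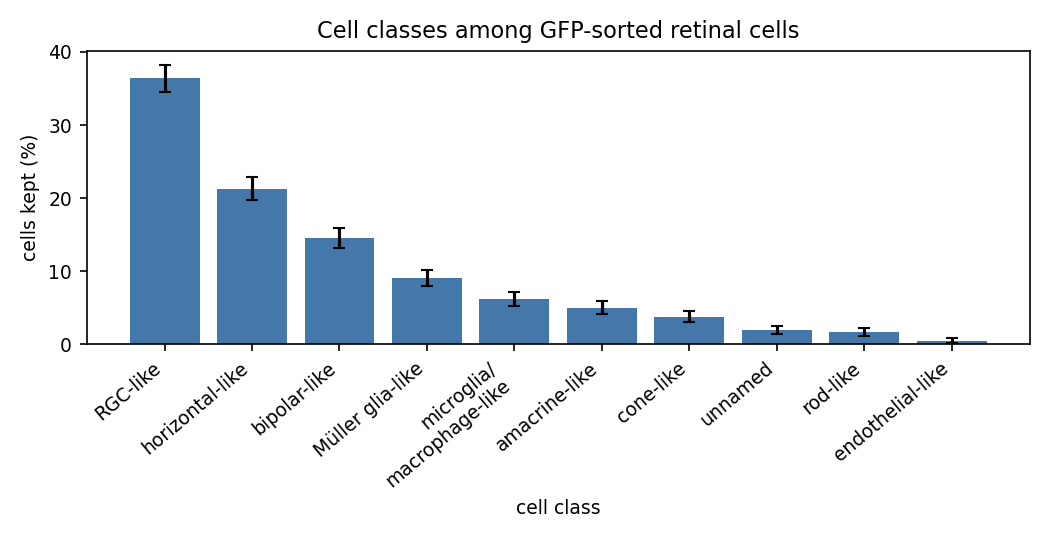
Share of each cell class among the 2636 cells kept, in percent. Bars are named from marker genes and whiskers are 95% Clopper-Pearson intervals for counting error; RGC-like cells reach 36.4% and horizontal-like cells 21.3%.

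The sort used a Pou4f2 reporter, so the next comparison asked how many RGC-like cells carried transcripts of each of the 3 POU4F transcription factor genes. Pou4f1 was found in more RGC-like cells than Pou4f2. At 12000 UMIs per cell, 86.8% of 730 RGC-like cells had a Pou4f1 UMI (interval 84.2% to 89.2%), 52.5% a Pou4f2 UMI (48.8% to 56.1%) and 35.6% a Pou4f3 UMI (32.1% to 39.2%). In 175 horizontal-like cells thinned to the same depth, the shares were 5.71% for Pou4f1 and 4.57% for Pou4f2. None of these 175 cells had a Pou4f3 UMI, which allows a share of up to 1.71%. The undetected share still includes cells that transcribe the gene: without thinning, at a median of 15365 UMIs, Pou4f2 was detected in 57.9% of RGC-like cells.

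The order of the genes and the gap to other classes held at a depth that every cell reached. At 3000 UMIs, Pou4f2 was detected in 20.4% of the 959 RGC-like cells, 0.178% of the 561 horizontal-like cells and 0.657% of the 1066 cells of the other named classes. The corresponding shares for Pou4f1 were 65.2%, 2.32% and 3.66%. Pou4f1 (mm10: ENSMUSG00000048349, chromosome 14, 104461676 to 104467999), Pou4f2 (ENSMUSG00000031688, chromosome 8, 78433010 to 78436645) and Pou4f3 (ENSMUSG00000024497, chromosome 18, 42394539 to 42397249) are protein-coding genes on separate chromosomes.

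Pou4f3 was almost always found together with Pou4f1. Of the 260 RGC-like cells with a Pou4f3 UMI, 145 had Pou4f1 and no Pou4f2, 111 had all 3 genes, 3 had neither of the others and 1 had Pou4f2 alone beside it. Pou4f1 was itself found in 86.8% of RGC-like cells. Pou4f3 without the others was seen in 0.411% of cells, against 2.23% if the 3 genes were independent. With Pou4f2 but not Pou4f1 it was 0.137% against 2.46%. With Pou4f1 but not Pou4f2 it was 19.9% against 14.7%, and all 3 genes were seen in 15.2% against 16.2%. For Pou4f2 the shares lay nearer to independence: 219 cells (30%) had Pou4f1 and Pou4f2 without Pou4f3, against 29.3%. Pou4f2 only was seen in 52 cells (7.12%), against 4.44%. Pou4f1 alone was seen in 159 cells (21.8%), and 40 cells (5.48%) had none of the 3.

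**Figure D2:**
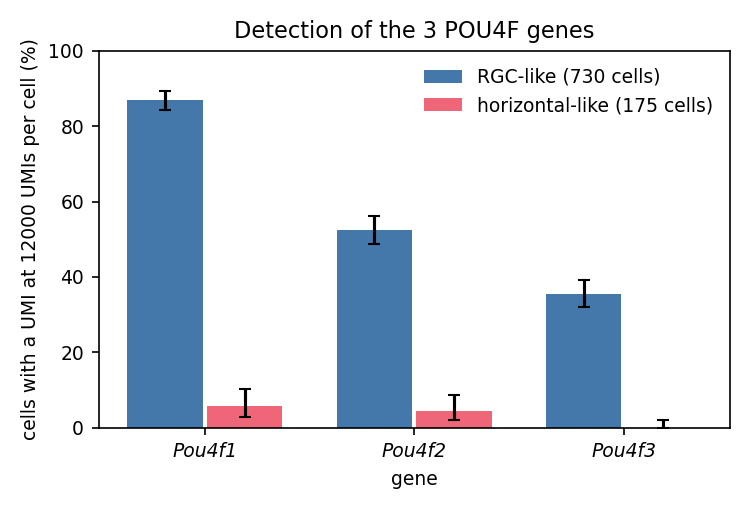
Percent of cells with a UMI of Pou4f1, Pou4f2 and Pou4f3 after thinning to 12000 UMIs, in RGC-like and horizontal-like cells. Whiskers are 95% Clopper-Pearson intervals; Pou4f1 reaches 86.8% in RGC-like cells and 5.71% in horizontal-like cells.

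The 3 POU4F genes had different peaks among the 22 RGC-like clusters. Pou4f1 was highest in cluster 13 at 1187 CPM (1078 to 1303) and lowest in cluster 12, the melanopsin cluster, at 29.2 CPM (17.3 to 46.2). Pou4f2 was highest in cluster 5, the Tbr1/J-RGC-like cluster, at 240 CPM (208 to 275). Pou4f3 was highest in cluster 8 at 275 CPM (243 to 311). Low Pou4f1 did not mean low Pou4f2: the Spp1 cluster 6 had 39.3 CPM (28.3 to 53.1) of Pou4f1 and 166 CPM (142 to 192) of Pou4f2. The Lmo2 cluster 3 was similar, with 91.2 CPM (75.6 to 109) of Pou4f1 and 156 CPM (136 to 179) of Pou4f2. Cluster 12 was low in all 3, with 27.6 CPM (16.1 to 44.2) of Pou4f2 and 2 UMIs of Pou4f3 in its 42 cells.

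**Figure D3:**
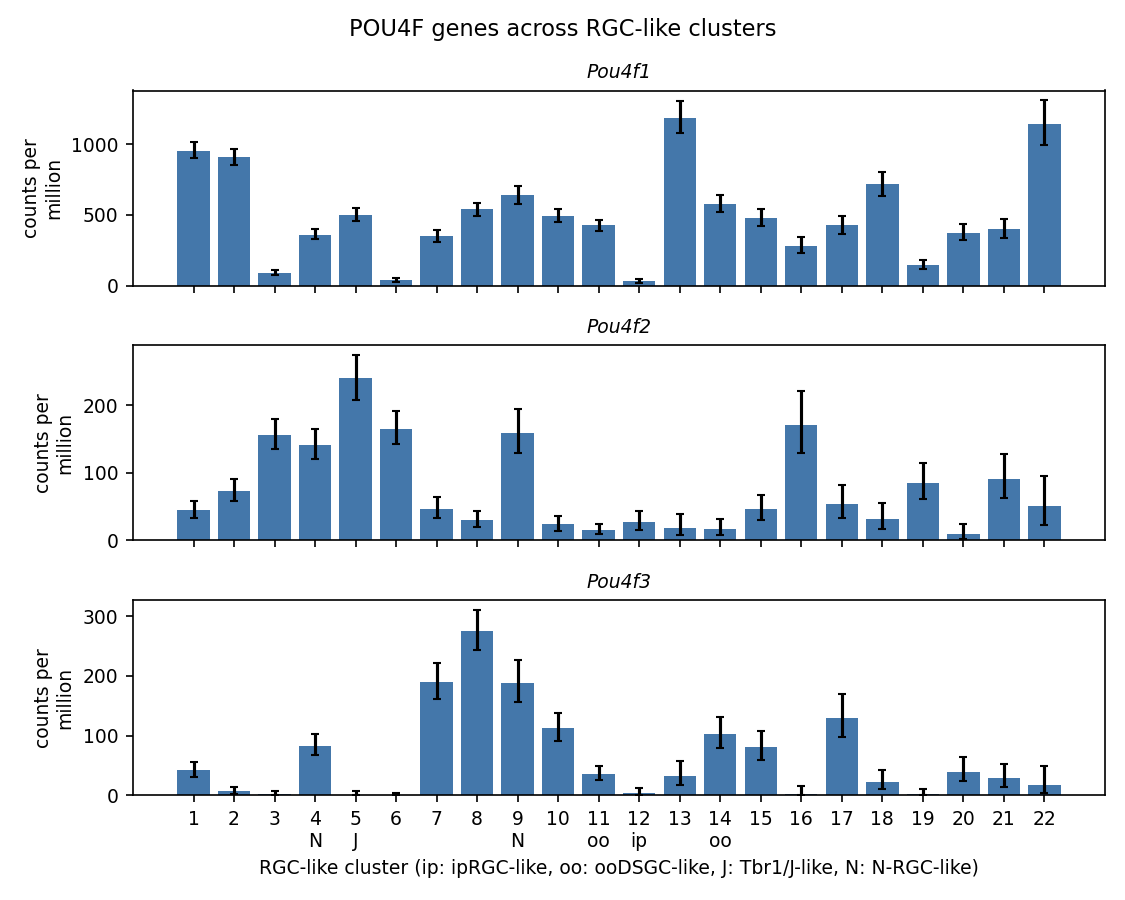
CPM of Pou4f1, Pou4f2 and Pou4f3 in each RGC-like cluster, with 95% Poisson intervals as whiskers. Pou4f1 spans 29.2 to 1187 CPM, Pou4f2 peaks in cluster 5 and Pou4f3 in cluster 8.

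The RGC-like cells were then compared with markers of known RGC types. Of the 22 clusters, 6 met the rule for a type. N-RGC-like cells made up 11.8% of RGC-like cells (clusters 4 and 9, interval 9.81% to 14.0%). ooDSGC-like cells made up 8.03% (clusters 11 and 14, 6.39% to 9.93%), Tbr1/J-RGC-like cells 6.36% (cluster 5, 4.90% to 8.10%) and ipRGC-like cells 4.38% (cluster 12, 3.17% to 5.87%). The other 16 clusters, with 69.4% of the cells, met no type's rule, and no cluster met the rule for F-RGCs, alpha RGCs or T5/W3-RGCs. The Foxp2 clusters 2, 21 and 22 each had 2 F-RGC markers raised. The Spp1 cluster 6 had 3 ipRGC markers raised, but its leading gene is on the alpha RGC list. The shares move with the settings. At resolution 0.5 ipRGC-like clusters held 13.1% and N-RGC-like clusters 4.43%. Under the stricter cell filter Tbr1/J-RGC-like clusters held 16.0% and ooDSGC-like clusters 14.1%, and with doublets kept ooDSGC-like clusters held 4.62%.

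Markers of the types were often shared between clusters. Opn4, the melanopsin gene, reached 1195 CPM (1110 to 1284) in cluster 12 against 25.5 CPM in all other RGC-like clusters together, of which cluster 6 was at 289 CPM (258 to 323), and Eomes reached 328 CPM (284 to 376) there, 116 CPM (96.5 to 138) in cluster 6 and 103 CPM (72.0 to 144) in cluster 16. Penk reached 667 CPM (604 to 735) in the N-RGC-like cluster 9 and 127 CPM (107 to 150) in cluster 4, but 533 CPM (464 to 609) in the unnamed cluster 18. Neurod2 was at 232 CPM (196 to 273) and 167 CPM (144 to 193) in clusters 9 and 4, and at 250 CPM (212 to 292) in the ooDSGC-like cluster 14. Both ooDSGC-like clusters were high in Cartpt by CPM, but cluster 11 had a median of 10 UMIs per cell against 118.5 in cluster 14. In cluster 11, 1 cell held 21.7% of the Cartpt UMIs. Several unnamed clusters had higher medians than cluster 11, such as 103 in cluster 7 and 47.5 in cluster 17. Cluster 14 carried the receptor gene Trhr at 118 CPM (92.4 to 148) and Mmp17 at 102 CPM (78.4 to 130). Cluster 11 carried the collagen gene Col25a1 at 39.7 CPM (28.9 to 53.1). Cartpt was nearly as high in cluster 7, at 8630 CPM (8430 to 8832) against 9252 CPM (9016 to 9493) in cluster 14. The 6313 CPM of cluster 12 came almost wholly from 1 cell, which held 97.6% of its Cartpt UMIs, and cluster 17 was at 3789 CPM. Cluster 7 had no other ooDSGC marker raised and kept no name. In cluster 5, Plpp4 reached 95.9 CPM (76.3 to 119) and Tbr1 76.0 CPM (58.7 to 96.9), while Tbr1 was higher, at 145 CPM (110 to 187), in the unnamed cluster 17.

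The functional lists were compared across the 20 RGC-like clusters of 20 or more cells to ask which kinds of gene set the clusters apart. Genes of the neuropeptide and secreted factor list, called neuropeptides for short below, had the highest median fold between clusters. That list also holds secreted factors such as Spp1 and Igf1. Adhesion and transcription factor genes followed, and axon cytoskeleton and mitochondrially encoded genes had the lowest. The median fold of the highest cluster over the mean of the others was 15.8 for neuropeptides, 3.99 for adhesion and guidance genes and 3.97 for transcription factors. It was 2.75 for transmitter receptors, 2.66 for calcium-binding proteins, 2.13 for voltage-gated channels, 2.12 for both injury genes and immediate-early genes, 1.53 for axon cytoskeleton genes and 1.49 for mitochondrially encoded genes. Counted over the lists, 62 memberships reached 4-fold: 18 of 37 transcription factors, 15 of 31 adhesion genes, 13 of 16 neuropeptides, 6 of 27 receptors, 3 of 13 calcium-binding proteins, 2 of 30 channels, 2 of 9 injury genes, 2 of 13 immediate-early genes, 1 of 15 cytoskeleton genes and 0 of 9 mitochondrially encoded genes. A gene in 2 lists is counted in both, and some members are also type markers. These folds were not set against random lists or all genes. A fold of the highest cluster can also be large where 1 cell holds most of the UMIs, as for Sst. The order of the lists therefore describes these members and does not show that a kind of gene sets the clusters apart.

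Single transcription factors marked clusters that had no type name. Zic1 reached 389 CPM (331 to 455) in cluster 18, 202-fold over the mean of the other clusters. Foxp2 was 67.0-fold higher in cluster 2, but 7.65-fold when the smaller Foxp2 clusters 21 and 22 are counted among the others. Lmo2 was 43.8-fold higher in cluster 3 and Tbx20 23.2-fold in cluster 16. Tbx20 was also at 131 CPM (104 to 163) in the ipRGC-like cluster 12 and 116 CPM (96.5 to 138) in cluster 6. Tbx20 cluster 16 also had the highest level of Prph, the intermediate filament gene peripherin, at 609 CPM (528 to 698), 16.2-fold over the mean of the others although cluster 6 had 507 CPM, and of the immediate-early genes Nr4a1 (4.09-fold) and Egr1 (4.04-fold). For Nr4a1 cluster 12 followed, at 55.2 CPM against 73.9 CPM, and for Egr1 as well, at 219 CPM against 331 CPM.

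Genes of the neuropeptide and secreted factor list marked other clusters. Spp1, which encodes osteopontin, reached 816 CPM (762 to 872) in cluster 6 against a mean of 11.7 elsewhere, 69.5-fold. Melanopsin cluster 12 had the highest level of Nmb (112-fold), which encodes neuromedin B, of Nppb (24.8-fold) and of Gal (23.0-fold). Of the 157 Nmb UMIs in RGC-like cells, 22.9% came from 1 cell of cluster 12. Npy peaked in cluster 19 (47.3-fold) and Calca in cluster 20 (26.9-fold), with 35.2% and 31.8% of the UMIs in those clusters from 1 cell each. Sst also met the rule in cluster 12, but 260 of its 267 UMIs in RGC-like cells came from 1 cell.

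Among adhesion and guidance genes, Pcdh20 peaked in the Foxp2 cluster 2 (15.1-fold), Cdh7 in cluster 15 (7.12-fold), Cdh12 in cluster 7 (6.59-fold), Unc5d in cluster 16 (5.82-fold) and Pcdh7 in cluster 10 (5.69-fold). Some of these peaks were close to another cluster. Cdh12 was at 38.7 CPM in cluster 7 and 36.5 CPM in cluster 6. Unc5d was at 145 CPM in cluster 16 and 117 CPM in cluster 6. Cluster 10 also had the highest S100b (13.2-fold, 38.8% of its UMIs there from 1 cell) and the highest level of the potassium channel gene Kcnd2, 319 CPM (282 to 359) or 8.25-fold. Calb1 peaked in the ooDSGC-like cluster 11 at 1010 CPM (952 to 1070, 7.61-fold). Pvalb peaked in cluster 20 (5.06-fold) at 1764 CPM, but clusters 10, 11 and 15 had 1581, 1504 and 1089 CPM. The nicotinic receptor genes parted, with Chrna4 highest in cluster 6 (8.12-fold) and Chrna3 in cluster 19 (7.31-fold). Chrna4 was at 74.8 CPM in cluster 6 and 52.9 CPM in cluster 3. Htr1b peaked in cluster 3 (5.13-fold), Grik3 in cluster 15 (4.53-fold) and Cacng3 in cluster 19 (4.22-fold). Grik3 was at 30.1 CPM in cluster 15 and 22.9 CPM in cluster 2.

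**Figure D4:**
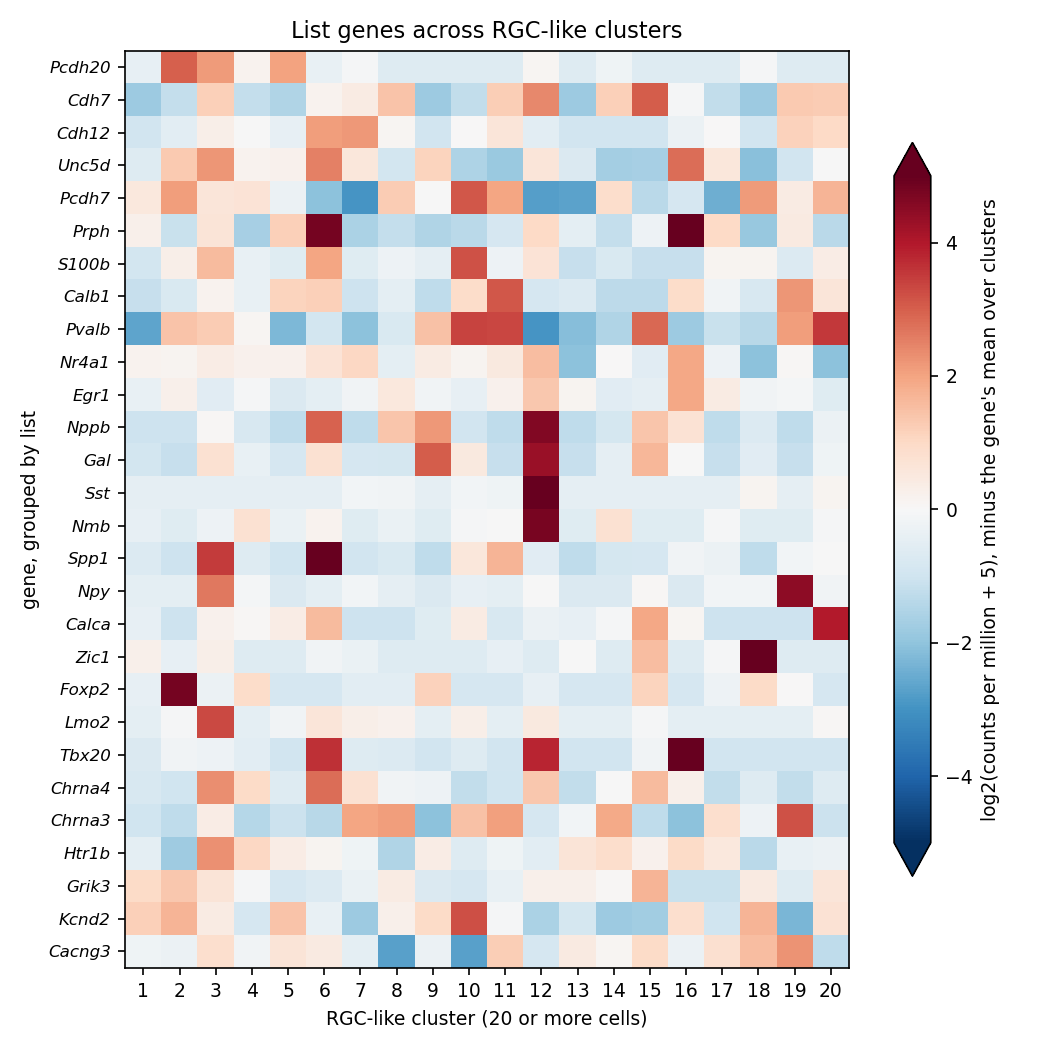
Level of list genes named in the text in the 20 RGC-like clusters of 20 or more cells, as log2 of CPM plus 5, less the gene's mean over clusters. Red is above the mean and blue below it; Zic1 stands out in cluster 18, Spp1 in cluster 6 and Foxp2 in cluster 2.

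The first division set 634 RGC-like cells with a Pou4f1 UMI against 96 without one. Cells without Pou4f1 carried the genes of the Eomes and melanopsin group. Opn4 was 13.4-fold (11.7 to 15.3) higher in them, Eomes 7.23-fold (5.93 to 8.82) and Spp1 8.16-fold (7.25 to 9.20). Cells with Pou4f1 had higher Tusc5, 33.7-fold (21.5 to 56.0), and higher Pou4f3, 22.9-fold (10.5 to 62.7). These ratios depend on depth: at 6000 UMIs the median log2 ratio of the 12 genes highest with Pou4f1 was 1.70, in place of 4.48, and 4 of the 12 were shared. Pou4f2 went the other way and was 1.52-fold (1.30 to 1.76) higher in cells without Pou4f1. Of the 96 cells without Pou4f1, 59.4% had an Eomes UMI and 55.2% an Opn4 UMI in the full counts, against 11.5% and 8.36% of the cells with it.

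Among the 12 genes highest with Pou4f1 were Phgdh, which encodes an enzyme of serine synthesis, Penk, Tusc5, Foxp2, Pou4f3, the cystine transporter gene Slc7a11, Tfap2d, Gm15825, Crh, Bcl11b and Il12a. Of these, Tusc5, Pou4f3 and Il12a had more than 3 UMIs in the cells without Pou4f1. The ratios of the others therefore have wide intervals, such as 34.3-fold (11.7 to 167) for Penk, and 45.1% of the Crh UMIs came from 1 cell. The 12 lowest were Sst, Cd24a, Opn4, Rasgrp1, Nppb, Ifitm10, Prkcq, Spp1, Lsp1, A230065H16Rik, Dgkg and Nmb. Apart from Sst, which rested on 1 cell, they were between 7.62-fold and 13.7-fold lower in cells with Pou4f1.

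Of the functional and type list members, 46 reached a ratio of 1.5 with Pou4f1 and 38 without it. The share of all 9129 ranked genes that reached 1.5 is not given here. Such counts, in this and the later divisions, therefore have no background to be read against. Higher with Pou4f1 were the adhesion gene Cdh4 (12.8-fold, 6.45 to 29.7), the transcription factor genes Isl2 (9.88-fold, 5.86 to 18.1), Lmo4 (8.28-fold, 5.49 to 13.1) and Meis2 (5.65-fold, 4.00 to 8.25), and Calb2 (5.46-fold, 5.22 to 5.71), which encodes calretinin. Higher without Pou4f1 were the growth factor gene Igf1 (4.64-fold, 4.19 to 5.13), Cck (4.56-fold, 4.08 to 5.09) and the receptor gene Chrna4 (6.07-fold, 4.57 to 8.06). The median log2 ratio of the transcription factor list was 0.58 (percentile 100 of matched random lists) and that of the neuropeptide list -1.66 (percentile 0). Smaller medians were found for calcium-binding genes, 0.33 (99.98), immediate-early genes, 0.22 (98.3), receptors, 0.16 (98.9), and adhesion genes, -0.10 (4.78). The medians of injury genes, 0.03 (62.8), channels, -0.01 (33.4), cytoskeleton genes, -0.01 (71.1), and mitochondrially encoded genes, -0.01 (67.0), were near 0. The mean had the opposite sign for injury genes (-0.36), channels (0.07) and mitochondrially encoded genes (0.01).

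Eomes, also called Tbr2, marks a group of RGCs that includes the melanopsin cells, and the second division set 114 cells with an Eomes UMI against 616 without. Cells with Eomes were higher in Opn4, 27.1-fold (23.1 to 32.1), in Tbx20, 22.0-fold (16.5 to 29.7), in Spp1, 17.9-fold (15.6 to 20.6), and in Prph, 15.7-fold (13.4 to 18.5). They were lower in Cartpt, 13.2-fold (11.8 to 14.7) with 14.6% of its UMIs in 1 cell, in Pou4f3, 10.8-fold (6.51 to 19.4), and in Pou4f1, 3.72-fold (3.30 to 4.21). Pou4f2 was 1.92-fold (1.68 to 2.2) higher. An Eomes UMI was found in 15.6% of RGC-like and 0.571% of horizontal-like cells at 12000 UMIs, and 46 of the 114 cells had exactly 1. Eomes lies on chromosome 9 (ENSMUSG00000032446, 118478212 to 118486132).

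The 12 genes highest with Eomes were Cd24a, which encodes a surface glycoprotein and was 34.9-fold (25.6 to 48.3) higher, A230065H16Rik, Opn4, Tbx20, Lsp1, Spp1, Prkcq, Nmb, Prph, Ifitm10, 1700011I03Rik and Igfbp2 (11.4-fold). Opn4 was found in 59.6% of the cells with Eomes, Tbx20 in 50%, Prph in 41.2%, Spp1 in 24.6% and Nmb in 14.0%. Of 10 pairs of these genes, 8 were found together more often than independence gives, such as Opn4 and Tbx20 in 44 cells against 34 and Prph and Spp1 in 24 against 11.5. Nmb was found with Prph in 4 cells against 6.60 and with Spp1 in 2 against 3.93. The 12 lowest were Foxp2, Fam163a, Crh, Sst, Phgdh, Tbr1, Cartpt, 1700007G11Rik, Bcl11b, Pou4f3, Tfap2d and Gm12027. Foxp2 had 2 UMIs in the cells with Eomes and was 37.4-fold (10.3 to 310) lower. Crh had 1 UMI in the cells with Eomes, and Tbr1 and 1700007G11Rik had 2 each. Sst had 0 UMIs there and was at least 15.8-fold lower, a value set by the 1 cell that held most of its UMIs.

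Of the list members, 31 were higher and 60 lower by 1.5-fold or more with Eomes. Pcdh19 (4.77-fold, 3.93 to 5.77), Igf1 (3.90-fold, 3.53 to 4.32), the GABA receptor gene Gabra3 (3.67-fold, 2.94 to 4.57) and Nppb (11.2-fold, 8.84 to 14.3) were higher. Pvalb (8.47-fold, 7.11 to 10.2), Isl2 (7.77-fold, 5.05 to 12.6), Tusc5 (6.29-fold, 5.24 to 7.62), Chrna3 (5.32-fold, 3.19 to 9.59) and Pcdh7 (5.10-fold, 3.97 to 6.65) were lower. The list medians were 0.47 for neuropeptides (percentile 100), 0.22 for adhesion genes (99.98), -0.43 for transcription factors (0) and -0.40 for receptors (0). They were -0.16 for channels (0.5), -0.17 for calcium-binding genes (2.84), -0.17 for mitochondrially encoded genes (1.40), -0.18 for injury genes (5.60), -0.11 for immediate-early genes (15.8) and 0.04 for cytoskeleton genes (56.6). The mean had the opposite sign for adhesion genes (-0.07) and injury genes (0.39).

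Foxp2 marks the F-RGCs, and the third division set 105 cells with a Foxp2 UMI against 625 without. In cells with Foxp2, Spp1 was 33.8-fold (14.5 to 104) lower, Irx6 11.5-fold (7.15 to 19.8), the glutamate receptor gene Grin2a 6.98-fold (4.39 to 11.8) and Eomes 5.53-fold (3.06 to 11.2). The LIM-domain gene Lmo4 was 3.89-fold (3.47 to 4.36) higher and was found in 90.5% of Foxp2 cells against 53.4% of the others. Pou4f1 was 1.77-fold (1.66 to 1.89) higher and Pou4f3 2.50-fold (1.89 to 3.36) lower. The ratio for Pou4f2, 0.841 (0.694 to 1.01), had an interval that includes 1. Foxp2 (ENSMUSG00000029563, chromosome 6, 14901349 to 15441977) was detected in 14.4% of RGC-like and 1.14% of horizontal-like cells at 12000 UMIs.

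The 12 genes highest with Foxp2 were Crh, Coch, Lor, Spon1, Phgdh, Gas7, Pcdh20, Gm13373, Gm26812, Lmo4, Lpl and the kainate receptor gene Grik3 (3.30-fold). Some rested on few cells. Coch, 14.2-fold (11.4 to 17.6) higher, and Lor, 8.04-fold (6.84 to 9.45), were found in 17.1% and 25.7% of Foxp2 cells against 12.2% and 32.8% of the others, and both lead the 17-cell cluster 21 with Crh. Spon1 (5.64-fold, 4.76 to 6.66), Phgdh (5.10-fold, 4.11 to 6.33) and Lpl (3.66-fold, 2.80 to 4.76) were more widespread, in 64.8%, 43.8% and 43.8% of Foxp2 cells. The 12 lowest were Sst, Spp1, A230065H16Rik, Ccer2, Ctxn3, Cdkn1c, Prph, Hs3st4, 1700011I03Rik, Irx6, Tbr1 and Igfbp5. In Foxp2 cells, A230065H16Rik and Ccer2 had 1 UMI each, and Hs3st4 and Tbr1 had 2 each. Their ratios have wide intervals, such as 30.9-fold (5.49 to 1227) lower for A230065H16Rik. Sst and Cdkn1c had 97.4% and 58.3% of their UMIs in a single cell each, and Sst reversed under the stricter cell filter. Ctxn3 was 27.5-fold (16.9 to 48.3) lower, and 1700011I03Rik, with 0 UMIs in Foxp2 cells, at least 11.7-fold lower.

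Of the list members, 25 were higher and 61 lower by 1.5-fold or more with Foxp2. Tusc5 (3.16-fold, 2.96 to 3.37) and the F-RGC markers Irx4 (2.23-fold, 1.84 to 2.68) and Foxp1 (2.04-fold, 1.65 to 2.50) were higher. Cartpt (5.82-fold, 5.39 to 6.29), Cck (5.42-fold, 3.89 to 7.77), Cntn5 (3.67-fold, 2.30 to 6.25) and Calb1 (3.43-fold, 2.85 to 4.17) were lower. Cartpt was nevertheless found in 86.7% of Foxp2 cells against 88.2% of the others, and a single cell held 14.6% of its UMIs. The list medians were -0.99 for neuropeptides (percentile 0), -0.37 for receptors (0), -0.37 for adhesion genes (0), -0.36 for transcription factors (0) and -0.19 for channels (0). They were 0.27 for injury genes (99.93), 0.19 for immediate-early genes (99.86), -0.12 for mitochondrially encoded genes (1.84), -0.04 for calcium-binding genes (17.9) and -0.03 for cytoskeleton genes (21.0). The means of all 10 lists had the sign of their medians.

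Cartpt encodes a neuropeptide of ON-OFF direction-selective RGCs, and the last division set 609 cells with a Cartpt UMI against 121 without. A Cartpt UMI is a weak criterion here, because its RNA was widespread: 83.4% of RGC-like cells but also 50.3% of horizontal-like cells had one at 12000 UMIs, and 135 of the 609 cells had exactly 1. A criterion of 10 or more UMIs, chosen after these values were seen, was met by 174 of 730 RGC-like cells (23.8%, interval 20.8% to 27.1%) and by 0 of 175 horizontal-like cells, which allows up to 1.71%. Cells with 10 or more Cartpt UMIs were higher than cells with none in the transcription factor gene Tfap2d, 27.1-fold (13.0 to 68.1), in Chrna3, 11.1-fold (6.49 to 20.6), and in Pou4f3, 4.48-fold (3.50 to 5.81). They were lower in Eomes, 19.2-fold (9.75 to 43.2), in Spp1, 21.1-fold (14.0 to 33.5), in Prph, 15.8-fold (10.5 to 24.6), and in Pou4f2, 2.89-fold (2.36 to 3.56). Pou4f1 did not differ beyond counting error, at a ratio of 0.983 (0.905 to 1.07).

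By the planned criterion of 1 UMI the same directions were seen with smaller ratios. Tfap2d was 9.73-fold (4.67 to 24.4) higher, Chrna3 6.10-fold (3.59 to 11.2) and Pou4f3 2.21-fold (1.74 to 2.85), and Eomes was 1.85-fold (1.47 to 2.32) lower, Prph 2.48-fold (2.13 to 2.89) and Pou4f2 1.62-fold (1.40 to 1.86). The ratio for Pou4f1 was 1.06 (0.985 to 1.13). Spp1 was 2.06-fold (1.80 to 2.35) lower, but higher when the cells were not thinned. Among the 12 highest genes were Sst, Tfap2d, A930017K11Rik, Cidea, Chrna3, Gm15825, the thyroid hormone receptor gene Thrb, Gm17750, Fam163a, Serpinb1b and Runx1. Sst rested on 1 cell and reversed under other settings, and Cidea, with 0 UMIs in cells without Cartpt, was at least 7.38-fold higher. A930017K11Rik had 2 UMIs in cells without Cartpt. Among the 12 lowest were Cdkn1c, S100b, Tbx20, Dgkg, Prph, Synpr, Plpp4, Pcdh20, 1700011I03Rik, Crip2 and Spag5. Cdkn1c, which encodes a cell cycle inhibitor, was 14.3-fold (11.2 to 18.3) lower, but 58.3% of its UMIs came from 1 cell. Cartpt lies on chromosome 13 (ENSMUSG00000021647, 99898489 to 99901091).

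By the same criterion, 17 list members were higher and 17 lower by 1.5-fold or more with Cartpt. Gabrg3 (2.58-fold, 1.95 to 3.48), Gabra2 (2.10-fold, 1.75 to 2.54) and Neurod2 (2.09-fold, 1.49 to 3.01) were higher, and Unc5d (1.94-fold, 1.55 to 2.42) and Jam2 (1.83-fold, 1.51 to 2.21) were lower. The list medians were 0.17 for receptors (percentile 99.98), 0.17 for mitochondrially encoded genes (99.99), 0.13 for immediate-early genes (99.58), 0.04 for channels (84.0) and 0.02 for adhesion genes (59.3). They were -0.26 for neuropeptides (0), -0.05 for cytoskeleton genes (7.57), -0.03 for transcription factors (17.5), -0.01 for calcium-binding genes (48.5) and -0.0042 for injury genes (44.0). The mean had the opposite sign for transcription factors (0.05) and neuropeptides (0.05).

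**Figure D5:**
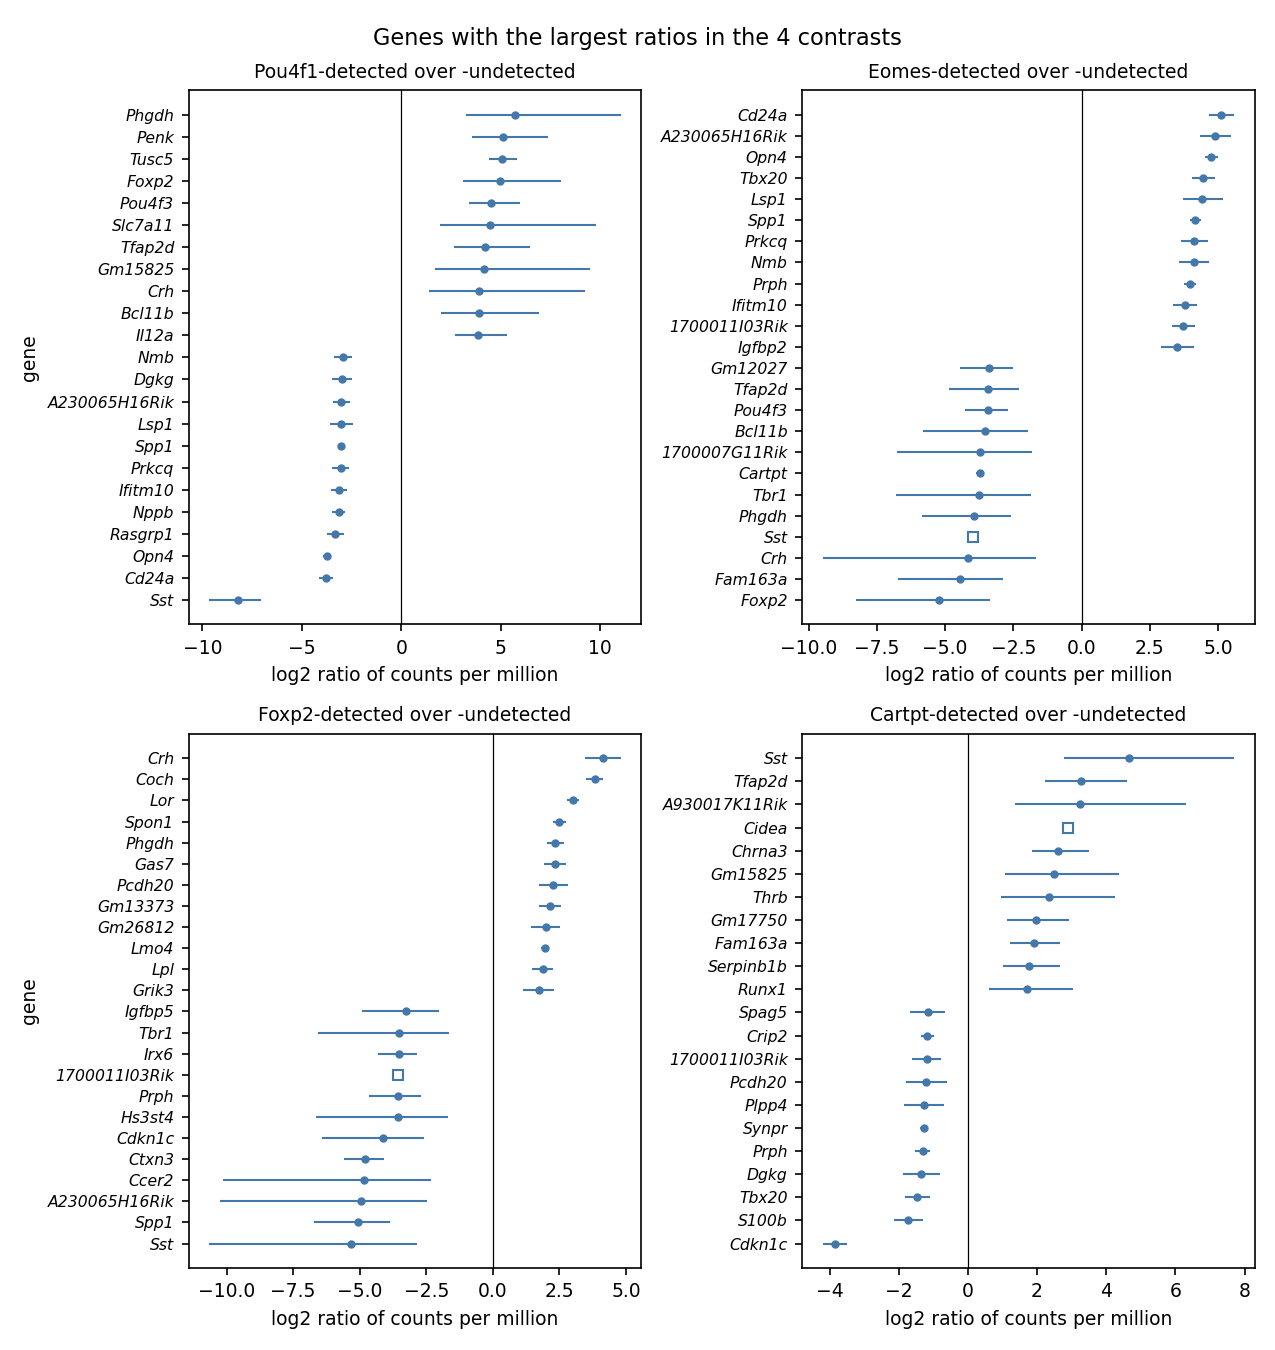
Log2 ratio of CPM, cells with the gene over cells without it, for genes among the 12 highest and 12 lowest in each of the 4 divisions of RGC-like cells. Lines are exact 95% intervals for counting error and open squares are bounds against a floor of 3 counts; Opn4 is at 4.76 with Eomes and at -3.74 with Pou4f1.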

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

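The comparisons of RGC marker levels and Pou4f2 levels were chosen after the results they address were seen, and the tests on the lowest UMI count and on the quartiles of the rod markers were set before their results.

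Barcodes removed by the cell filter carried class signals that the report's comparisons do not use. When clustered without the filter, 533 removed barcodes that were not called doublets fell among the classes: 332 with bipolar-like cells, 57 with horizontal-like cells and 16 with RGC-like cells. The 332 make up 62.3% of these barcodes (interval 58.0% to 66.4%) and 49.7% of the 668 bipolar-like barcodes. Their median mitochondrial share was 12%. The 16 barcodes with RGC-like cells had a median mitochondrial share of 36.5% and a median of 3919 UMIs. The filter therefore takes bipolar-like cells far more often than RGC-like cells, of which it takes 1.63%.

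Horizontal-like cells made up more than 20% of the cells kept from a sort for a Brn3b reporter, and 3 accounts were weighed. Doublets of a horizontal cell and an RGC are argued against, since the median level of the RGC markers in horizontal-like cells was 3.49% of that in RGC-like cells. Transcription of Pou4f2 in horizontal-like cells at the time of the sort is also argued against: its level was 2.27 CPM (interval 1.24 to 3.80), against 2.52 CPM (1.34 to 4.30) in the other classes that are not RGC-like and 84.0 CPM in RGC-like cells. A lowest UMI count that removes RGC-like cells is argued against as well, since 2.40% of RGC-like cells lay within 1.5 times the lowest count of all barcodes, near the 2.67% of horizontal-like cells. What stays open is a sort gate that let GFP-negative cells through and reporter protein left from earlier expression, neither of which was tested. Shares of the small cells are limited by that lowest count: 79.6% of cone-like, 78.4% of microglia or macrophage-like and 69.6% of bipolar-like cells lay within 1.5 times of it. No other explanation was tested.

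Another pattern was the pair of clusters, of 34 and 16 cells, that carried rod genes beside the markers of RGC-like or horizontal-like cells. A rod or rod fragment in the same droplet is consistent with the levels of 11 rod markers, which were raised to nearly the same part of their rod-like level. The median part was 7.26% in the RGC cluster and 8.45% in the horizontal cluster, and the upper quartile was 1.12 and 1.30 times the lower. Cells attached to a piece of rod and droplets that caught both were not told apart by this test, free rod RNA spread over all barcodes is not weighed here, and no biological explanation was tested.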

How the results depend on the processing

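Cartpt classes by 10 or more UMIs, the rod-gene-led cluster counted as RGC-like, class names by the median cluster and the 2 parts of the stricter filter alone were chosen after the data were seen.

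The stricter cell filter moved the class shares most. RGC-like cells became 65.4% and horizontal-like cells 3.90%. Its mitochondrial maximum of 5% alone gave the same shares, and its gene minimum of 1000 alone gave 36.4% and 21.3%. Without the filter the shares were 30.8% and 19.4%, as most removed barcodes joined other classes. Type shares depended on the grouping, and the cause was not tested. ooDSGC-like cells were 14.1% under the stricter filter, 4.62% with doublets kept and 4.33% with the rod-gene-led cluster added. Tbr1/J-RGC-like cells were 8.48% without the filter and 16.0% under the stricter one. N-RGC-like cells were 5.55% with doublets kept, 4.43% at resolution 0.5 and 8.86% at resolution 2.0, and ipRGC-like cells were 13.1% at resolution 0.5. F-RGC-like, alpha RGC-like and T5/W3-RGC-like clusters stayed at 0 in each setting run. The number of RGC-like clusters ranged from 16 to 25 and the list memberships at 4-fold or more from 51 to 65.

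Depth sets the share of cells with a UMI by construction. At 6000 UMIs the shares were 78.6% for Pou4f1, 37.2% for Pou4f2 and 24.0% for Pou4f3, and without thinning Pou4f2 was at 57.9% and Pou4f3 at 39.7%. Under the cell filters, with doublets kept and with the rod-gene-led cluster added, these shares stayed within their intervals. Their order was the same in each setting run.

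At 6000 UMIs the undetected class also takes in more cells that transcribe the gene. The median log2 ratio of the 12 genes highest with Pou4f1 was then 1.70 in place of 4.48, and that with Eomes 3.52 in place of 4.15, against 4.80 without thinning. The 12 lowest with Pou4f1 had a median of -3.53 under the stricter filter and -4.23 by 2 or more UMIs, in place of -3.08, and the 12 lowest with Cartpt -3.04 by 10 or more UMIs in place of -1.28. Of 2493 log2 ratios of named genes under the alternatives that can move them, 2155 stayed in their interval, 327 moved and 11 reversed. A ratio was counted as reversed only if its main log2 interval excluded 0, so the moved ratios include changes of sign. Nmb with Cartpt, for example, went from 0.61 to -1.20 by 10 or more UMIs. The reversals were Pcdh20 with Pou4f1 (0.034, stricter filter), Npy with Pou4f1 (1.60, no thinning), S100b with Eomes (-0.072, 6000 UMIs), Spp1 with Cartpt (1.61, no thinning), Crh with Cartpt (0.26 at 6000 UMIs, 1.14 without thinning) and Sst. Sst was at 1.19 with Eomes, 0.054 with Foxp2 and -0.87 with Cartpt under the stricter filter, and with Cartpt at -7.20 at 6000 UMIs and -0.69 by 10 or more UMIs. Sst moves with the class of 1 cell, and for the other genes the cause was not tested. Of 330 list medians, counted without the change of scaling, 307 stayed in their interval, 23 moved and 0 reversed. That interval was the median of the members' separate lower and upper bounds, which is not an interval for the list median. A reversal could be counted only where it excluded 0, so these counts do not measure how stable the medians are.

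The genes at each end also changed: at 6000 UMIs 4 of the 12 highest with Pou4f1 and 5 of the 12 lowest with each of Eomes, Foxp2 and Cartpt were shared. By 2 or more UMIs 6 of the 12 lowest with Eomes and 5 with Foxp2 were shared. For Cartpt, 5 of the 12 lowest were shared without thinning, 5 of the lowest and 6 of the highest by 10 or more UMIs, and 7 of the highest under the stricter filter. Without the low-count filter, between 0 and 12 of the 12 genes at each end were the same, since ratios of genes with few UMIs then fill the ends. Median-of-ratios scaling multiplies all ratios of a contrast by the same factor, so it shared all 12 at each end by construction. It shifted log2 ratios by at most 0.017. The tests planned per retina, the retina as a block and leaving out each retina were not run, because the matrix has no map from cells to retinas.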

Other observations

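No test was run in this part, and its genes and cells were chosen after their values were seen.

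Horizontal-like cells had their own profile across the functional lists. Onecut2 was at 728 CPM (707 to 750) in them, 78.8-fold over the mean of the other classes of 20 or more cells, and Lmo1 at 1245 CPM (1218 to 1273), 22.2-fold. The calcium channel gene Cacna1h was at 264 CPM (251 to 277, 14.5-fold), the adhesion genes Cdh4 and Sdk2 were 12.6-fold and 8.62-fold higher, and the dopamine receptor gene Drd1 was at 115 CPM (107 to 124, 6.15-fold). Both horizontal-like clusters carried these levels: Onecut2 was at 724 and 748 CPM, Drd1 at 116 and 113 CPM and Cacna1h at 265 and 258 CPM. Npy differed between them, at 131 CPM (interval 121 to 141) in the cluster of 447 cells and 90.6 CPM (73.5 to 110) in the cluster of 114.

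Most genes of the immediate-early list were highest in the glial and immune classes. Fos was at 3811 CPM (3700 to 3925) in Müller glia-like cells against 349 CPM in RGC-like cells, and Ier2 at 2768 CPM (2673 to 2865) against 80.7. Microglia or macrophage-like cells had the highest Junb, 4083 CPM (3938 to 4233), the highest Atf3, 1736 CPM (1642 to 1835), which was 46.4-fold over the mean of the other classes, and the highest Socs3, 695 CPM (636 to 759). Atf3, an injury-response gene, was at 11.7 CPM in RGC-like cells.

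Amacrine-like cells had 736 CPM (675 to 801) of Vip and 3296 CPM (3166 to 3430) of Cartpt, above the 1757 CPM of Cartpt in RGC-like cells. Bipolar-like cells had the highest Cacna2d3 at 1282 CPM (1231 to 1334) and the highest Isl1 at 905 CPM (863 to 950). Rod-like cells had the highest Drd4 at 394 CPM (309 to 494).

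An Sst-rich cell sat in the melanopsin cluster 12. It held 13117 UMIs, 260 of them Sst, with 0 UMIs of Opn4, Eomes, Pou4f1, Pou4f2, Rbpms and Slc17a6. Of the amacrine list it had 9 UMIs of Tfap2b, 4 of Gad1, 3 of Slc32a1 and 1 of Slc6a9, but 0 of Gad2 and Tfap2a, and it had 2 UMIs of the RGC marker Nefl. The remaining Sst UMIs in RGC-like cells were spread 1 per cell.

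The matrix has a feature for EGFP with 0 UMIs in 3237 barcodes, which allows a detected share of up to 0.0927%. Whether this feature matches the reporter in the mice was not tested, so the value does not limit how many cells transcribed the reporter. The female-specific transcript Xist had 2 UMIs in 2 barcodes, and the Y-linked gene Ddx3y had 2158 UMIs in 1440 barcodes. After thinning to 12000 UMIs, 44.4% of RGC-like cells had a Ddx3y UMI.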
